A study of Arabidopsis thaliana with 2 samples.

How the data were processed

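RNA was sequenced from hand-dissected mature ovules of Arabidopsis thaliana of 2 genotypes, with 1 library per genotype. The mutant myb98 lacks normal function of MYB98, a MYB transcription factor of the synergid cells, which flank the egg cell and attract pollen tubes. Per the labels, the wild-type library was made from ovules of the male-sterile line ms1 that had received no pollen, in place of true wild-type plants. Per the labels' protocols, flowers were emasculated at floral stage 12, ovules of about 50 pistils were collected 36 hours later, total RNA was purified with a column kit, and libraries were made for the Illumina HiSeq 2000. The accession background of either line and the hour of harvest are not given in the sources used here.

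The values used are FPKM (fragments per kilobase of transcript, scaled to the size of the library), as the authors deposited them in a table with 1 column per library. The table's header names only the libraries. The unit was read from the values, which were not whole numbers, and from the lowest values of transcripts, which scaled inversely with transcript length as FPKM do. TopHat2 2.0.14, Cuffdiff 2.2.1 and the TAIR10 genome are named in the submitters' processing notes. The annotation version, library strandedness, Cuffdiff options and any scaling between the libraries are not given in the sources used here. Cuffdiff assigns fragments to transcripts by an estimate, so a value of exactly 0 can be a failed estimate, and such genes are given as listed at 0 with no fold. FPKM are relative within a library, so a very abundant RNA lowers all others.

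The table held 35548 identifiers. Values were blank in both libraries for 1991 of them, 1973 of which carried a transcript suffix, and 33557 had values. Of these, 32810 matched a locus of the reference annotation (assembly TAIR10.1) and 747 did not. Gene names, transcript lengths and coordinates are those of TAIR10.1.

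No read counts were used. The depth was estimated from the lowest values above 0 of genes with a lone annotated transcript of at least 1500 nt. On that estimate, 1 fragment was worth 0.0210 FPKM per kilobase of transcript in the wild-type library and 0.0239 in the myb98 library, which corresponds to about 47500000 and 41800000 fragments. For short transcripts a fragment is worth more than this rule gives, because few fragment positions fit in them, so folds of short genes near the floor were not printed.

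With 1 library per genotype there is no estimate of replicate error, no p-value and no standard error. Genes were compared by a fixed rule of size, which is not a test. The log2 ratio was log2((myb98 FPKM + 1)/(wild-type FPKM + 1)), with a pseudocount of 1, which understates the change of low genes. Folds given beside it are plain ratios of FPKM. A gene was expressed if it had at least 1 FPKM in either library or both. Expressed genes with a log2 ratio of 2 or more in size, 4-fold on the pseudocount scale, are said to have fallen or risen in the myb98 library. A gene with a low wild-type value could not fall by this rule even if its transcript was absent from the myb98 library.

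The named genes were MYB98, every measured LURE1 gene, the 12 largest falls and 12 largest rises among nuclear genes with at least 5 FPKM in either library, and the 4 measured members of each gene list with the largest log2 ratio in size. Further members of the lists, and DD11, DD18 and FKF1, are named as well and were chosen after their values were seen. The rule, the lists, the size rule and the first set of other settings were fixed before the data were examined. There were 15 lists by gene identifier (LURE1 peptides, synergid function, egg cell, central cell, endosperm after fertilization, integument and ovule identity, carpel with stigma and transmitting tract, photosynthesis, pollen and pollen tube, jasmonate, touch and wound response, heat shock, salicylate defence, circadian clock, senescence). There were 12 lists by name pattern in the annotation (defensin-like, ECA1 gametogenesis related, thionin-like, lipid transfer, self-incompatibility homologs, RALF, pectin methylesterases and inhibitors, arabinogalactan proteins, subtilases, ribosomal proteins, histones, AGAMOUS-like). The thionin pattern was corrected after the data were seen, because it also matched methionine. The use of the annotation's note field for the 6 lists of small secreted proteins was likewise chosen then. Members with DUF784, DUF1278 or S1 domains were grouped after the data were seen.

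For each list, the median log2 ratio of its expressed members is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is no test of genotype. The median was taken over expressed members after the data were seen, because over all measured members it was 0 for most lists by name pattern. A second percentile, matched also on transcript length in 10 bins, was added after a trend with length was seen. Exon overlaps came from bedtools 2.31.1 and similar transcripts from blastn 2.17.0. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

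The size rule was tested on simulated data with a spread of 0.5 (SD of log2) between libraries, over 16154 expressed genes. It recovered 86% of 50 simulated 8-fold falls, 20% of 4-fold falls, 0% of 2-fold falls and 96% of 8-fold rises, and it called 0 unchanged genes. The changes were placed only in genes with a mean of at least 5 FPKM. Every gene had the same noise, with no failed estimates and no length trend. The 0 therefore follows from that setting and gives no rate of false calls in the real libraries. Of simulated lists with no change, 5.0% lay below the 5th percentile. The other settings fixed beforehand were pseudocounts of 0.1 and 5, no expression filter or one at 5 FPKM, size rules at log2 of 1 and 3, centring on the median ratio, a trimmed mean with 30% of ratios removed at each end, and equal nuclear totals. Settings added after the data were seen left out transcripts under 200 nt, kept protein-coding genes, centred each gene on genes of similar transcript length, rescaled to the nuclear total without ribosomal RNA, or matched names without the note field. Genes of similar or own transcript length were those of a running median over 401 genes by length. For transcripts under 300 nt this median drew mainly on longer genes.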

Results

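The series measured RNA in mature ovules of 2 genotypes, wild-type (unpollinated male-sterile ms1 ovules) and myb98, in FPKM with 1 library each. The libraries held about 47500000 and 41800000 fragments by estimate. At least 1 FPKM was reached by 15742 genes in the wild-type library and 15775 in the myb98 library, and 16303 genes reached it in either or both. There are no replicates, so no difference given here has a replicate check. Over the 8732 genes with at least 5 FPKM in both libraries, the log2 ratio had an SD of 0.47 across genes, and the middle of the distribution ran from -0.24 to 0.30 (interquartile range).

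MYB98 (AT4G18770), the mutated gene, lies on chromosome 4 at 10311030 to 10313104, plus strand, with 3 exons (TAIR10.1). Its transcript stood at 1.35 FPKM in the wild-type library and 0.474 FPKM in the myb98 library, so 35.1% remained (log2 ratio -0.67). These values correspond to about 120 and 37.0 fragments by the depth estimate. The direction goes with the labels. The gene did not pass the size rule, but at 1.35 FPKM in the wild-type library it could not have fallen by it. With the pseudocount, even a complete loss would be too small. Its annotated exons overlap those of AT4G18780 on the opposite strand, and without stated strandedness reads of the overlap cannot be assigned.

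The comparison of myb98 with wild-type ovules asks which transcripts of the ovule depend on MYB98, with cysteine-rich peptides as the subject of the series. The LURE1 genes, which encode defensin-like peptides that synergids secrete to attract pollen tubes, had the lowest median of the lists examined. LURE1.2 (AT5G43510) went from 191 FPKM to a listed 0, LURE1.4 (AT5G43518) from 81.7 FPKM to a listed 0, and AT4G08869 (LURE1.7) from 101 FPKM to a listed 0. LURE1.3 (AT5G43513) went from 182 to 0.211 FPKM and LURE1.5 (AT5G43525) from 213 to 0.261 FPKM. Summed over the 7 genes, 837 FPKM in wild-type ovules became 25.8 FPKM in myb98 ovules, or 3.08%.

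**Figure D1:**
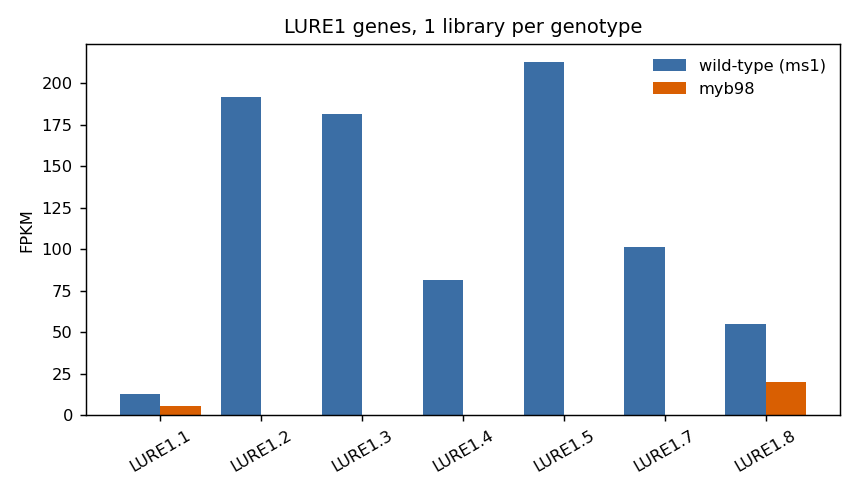
FPKM of the 7 LURE1 genes in the wild-type (ms1) and myb98 libraries, 1 library per genotype, with no error bars because there are no replicates. The 3 genes listed at 0 and LURE1.3 and LURE1.5 (0.211 and 0.261 FPKM) have no visible myb98 bar, while LURE1.1 and LURE1.8 keep 5.34 and 19.96 FPKM.

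By the size rule, 5 of the 7 LURE1 genes fell and 0 rose. The other 2 were lower by less than the rule asks. LURE1.1 (AT5G43285) had 12.9 and 5.34 FPKM (2.42-fold lower), and AT4G08875 (LURE1.8) had 54.9 and 19.96 FPKM (2.75-fold lower). The median log2 ratio of the list was -6.68, below all 10000 random lists, 95% of which lay between -0.35 and 0.41. LURE1.2 to LURE1.5 lie in a cluster on chromosome 5 from 17474049 to 17488516, each with 2 exons, and LURE1.1 lies at 17370473 to 17370857. AT4G08869 and AT4G08875 lie on chromosome 4 at 5657228 to 5659574 and 5673746 to 5674220. Values of single LURE1 genes are uncertain, since LURE1.2 and LURE1.5 transcripts are 98.5% identical and those of LURE1.3 and LURE1.4 95.5%. AT4G08869 and AT4G08875 also overlap exons of other annotated genes.

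Genes annotated as ECA1 gametogenesis related, a family of small secreted cysteine-rich proteins, fell in large number. Of 73 expressed members, 30 fell, 3 rose and 40 did not pass the rule, and the summed FPKM of the list went from 2429 to 866. At a log2 ratio of 1 or more in size, 37 were lower and 18 higher. AT5G42567 went from 119 to 0.134 FPKM, AT2G24205 from 121 to 0.280 FPKM, AT2G21727 from 107 to 0.0671 FPKM and AT1G57760 from 73.6 FPKM to a listed 0. The 3 that rose were AT5G36659, AT3G01323 and AT5G36470, of which AT3G01323 went from 5.87 to 29.9 FPKM. The AT5G36470 transcript is 100% identical to that of AT5G36450, and AT5G36659 is 97.9% identical to AT5G36661. Reads can be split within these pairs, so both rises are uncertain. The calls of AT5G36659 and AT3G01323 ended when each was set against genes of its own transcript length (log2 1.56 and 1.71). The median log2 ratio of the list was -1.15 (-0.51 with a pseudocount of 5). At a pseudocount of 1 it lay below all random lists matched on expression and below all those matched on length as well.

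Of the 30 falls in this list, 23 were of genes annotated with DUF784, a domain of unknown function, and 7 were not. Among the 7 were AT2G24205, AT5G60964 (76.4 to 0.898 FPKM) and AT5G54062 (27.5 to 0.102 FPKM), annotated as egg cell-secreted-like. The rest were AT1G45221 and the transcribed pseudogenes AT1G45227, AT1G45225 and AT5G44555. AT1G45221 is 99.8% identical to the DUF784 gene AT1G45215. AT1G45227 and AT1G45225 are 95.9% and 96.6% identical to the DUF784 gene AT1G45223. The grouping by DUF784 was made after the values were seen. Of 31 expressed DUF784 genes in the whole annotation, 28 fell and 0 rose (median log2 ratio -3.53, range -6.72 to -1.15), and 24 of the 31 are members of the ECA1 list. The other 3 were low in wild-type ovules, at 2.34 FPKM (AT5G42957), 2.30 FPKM (AT4G07515) and 1.22 FPKM (AT5G34887). AT3G11990 kept 10.9 of 111 FPKM (10.2-fold lower) and AT1G57777 10.7 of 108 FPKM (10.1-fold lower), while AT2G25482 went from 79.1 to 0.215 FPKM. Of 11 expressed genes with DUF1278, the domain of the egg cell EC1 peptides, 0 fell and 0 rose, with a median of 0.12 (range -1.72 to 1.55). Related DUF784 genes are similar in sequence (AT1G57760 and AT1G57777 90.2%), so reads can be split among them.

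Other small secreted proteins held both strong falls and members near or above their wild-type level. The defensin-like list, built from annotated names, held 2 of the LURE1 genes (AT4G08869 and AT4G08875) and not LURE1.1 to LURE1.5. At a log2 ratio of 1 or more in size, 7 of its 130 expressed genes were lower and 45 higher. By the size rule, 5 of the 130 fell, 7 rose and 118 did not pass, and with all LURE1 genes added 9 of 135 fell. AT5G50423 went from 73.1 to 0.230 FPKM, AT5G18403 from 55.1 to 0.238 FPKM, AT5G18407 from 39.3 FPKM to a listed 0, and AT5G48605 from 56.8 to 7.70 FPKM, and the remaining fall was AT4G08869. Matched without the note field of the annotation, the list had 1 fall. Its risers included LCR38 (1.26 to 11.7 FPKM) and AT1G35537 (0.281 to 7.90 FPKM), and the calls of the other 5 ended against genes of their own transcript length. For LCR20, at 268 nt, that comparison drew mainly on longer genes. The median of the expressed defensin-like genes was 0.64, above all random lists of either kind, and 0.20 after each gene was set against genes of its own transcript length.

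RALF genes, which encode small signalling peptides, had 13 expressed members, of which 2 fell and 0 rose. RALFL29 (AT4G11653) went from 84.8 FPKM and RALFL5 (AT1G35467) from 53.4 FPKM to a listed 0, while the list's median was 0.47 (percentile 99.9, and 87.6 with length matched). Of 27 expressed homologs of self-incompatibility proteins, 4 fell and 0 rose, with a median of 0.79 (above all random lists, and percentile 99.8 with length matched). Those that fell were AT1G56385 (91.2 to 4.81 FPKM, 18.9-fold), AT3G57840 (29.5 to 1.16 FPKM, 25.5-fold), AT5G04047 (47.2 to 4.75 FPKM) and AT3G17080 (5.83 to 0.201 FPKM). Of 40 expressed lipid transfer genes, 6 fell and 0 rose, with a median of 0.01 (percentile 32.4, and 0.85 with length matched). These 6 (AT5G42567, AT3G30383, AT5G34885, AT5G34881, AT5G42955 and AT1G45221) carry DUF784 or are in the ECA1 list. None of 15 expressed thionin-like genes passed the rule (median 0.50, percentile 99.8, and 69.2 with length matched).

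**Figure D2:**
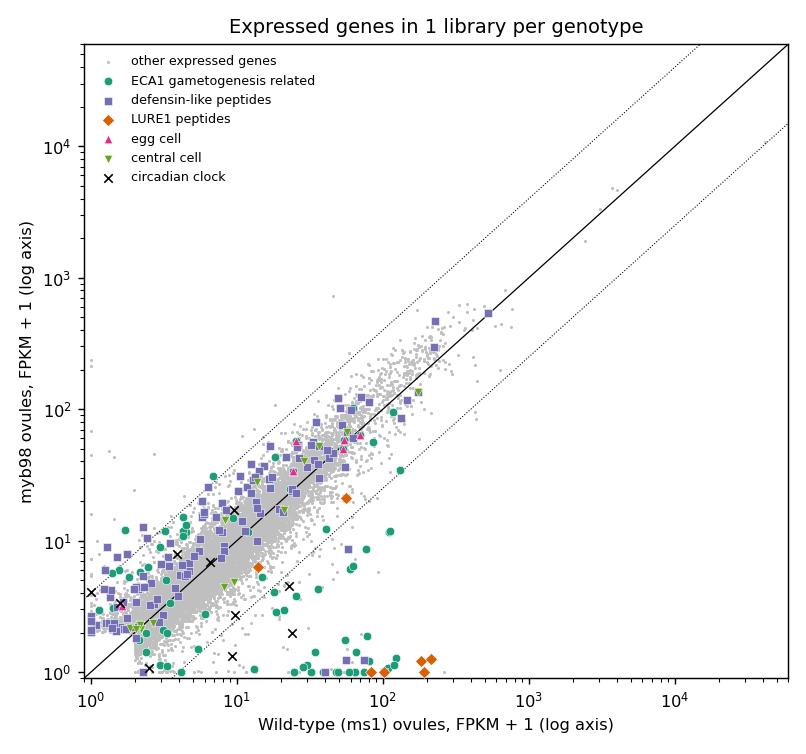
FPKM + 1 of each expressed gene in the wild-type library (horizontal, log axis) and the myb98 library (vertical, log axis), 1 point per gene, with 6 gene lists coloured. The solid line marks equal values and the dotted lines the size rule of 4-fold. The 5 fallen LURE1 genes and many of the 30 fallen ECA1-related genes lie along the bottom, the other ECA1-related genes lie nearer the solid line, and no egg cell or central cell marker lies beyond the dotted lines. Some of these markers are too low in the wild-type library to lie below the lower dotted line.

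Markers of the other cells of the ovule did not pass the rule. Some were too low in the wild-type library to fall by it. WOX8 of the egg cell was at 0.624 FPKM there. FWA, FIS2, MEA, AGL80 and ESF1.3 of the central cell were at 1.67, 1.21, 0.852, 1.18 and 1.05 FPKM. Among 6 expressed egg cell markers 0 fell and 0 rose (median 0.30, percentile 69.2, and 39.3 with length matched). Their median was -0.14 against genes of the same transcript length. EC1.1 (AT1G76750), an egg cell-secreted sperm activator, was at 68.9 and 62.7 FPKM and EC1.5 (AT5G64720) at 24.3 and 56.8 FPKM. Among 14 expressed central cell markers 0 fell and 0 rose (median 0.06, or -0.08 against genes of the same transcript length, percentile 48.8). The demethylase gene DME (AT5G04560) had 8.61 and 3.85 FPKM, AT1G26795 had 12.7 and 26.8 FPKM, and AT3G24510 had 173 and 134 FPKM. None of 14 expressed integument and ovule identity genes passed (median -0.22, percentile 1.7), among them the ovule identity gene STK (AT4G09960) at 106 and 123 FPKM and SHP1 (AT3G58780) at 40.1 and 29.1 FPKM.

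The list of synergid function genes had 10 expressed members, of which 1 fell and 0 rose (median 0.42, percentile 99.0, and 92.6 with length matched). The values are of whole ovules, so this median does not show how synergids alone expressed these genes. AT1G47470, a DUF784 gene, went from 64.9 to 0.422 FPKM. The receptor kinase gene FER (AT3G51550) had 43.9 and 42.7 FPKM, VDD (AT5G18000) 18.9 and 19.2 FPKM, ANNAT8 (AT5G12380) 4.80 and 1.68 FPKM and ENODL13 (AT5G25090) 16.2 and 34.9 FPKM. Outside the lists, and chosen after their values were seen, DD11 (AT1G52970) went from 70.2 to 0.956 FPKM and DD18 (AT1G45190) from 21.2 FPKM to a listed 0.

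Of tissues that dissection or pollination could add, 4 carpel, stigma and transmitting tract genes were expressed and 0 passed the rule (median 0.02, percentile 48.9), with ALC (AT5G67110) at 51.0 and 36.9 FPKM. In the pollen list 1 gene was expressed, ANX1 (AT3G04690) at 1.28 and 1.26 FPKM. In the list of endosperm after fertilization 1 gene was expressed, AGL62 (AT5G60440) at 0.90 and 1.32 FPKM. None of the salicylate defence genes was expressed, EDS1 (AT3G48090) being at 0.242 and 0.755 FPKM.

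**Figure D3:**
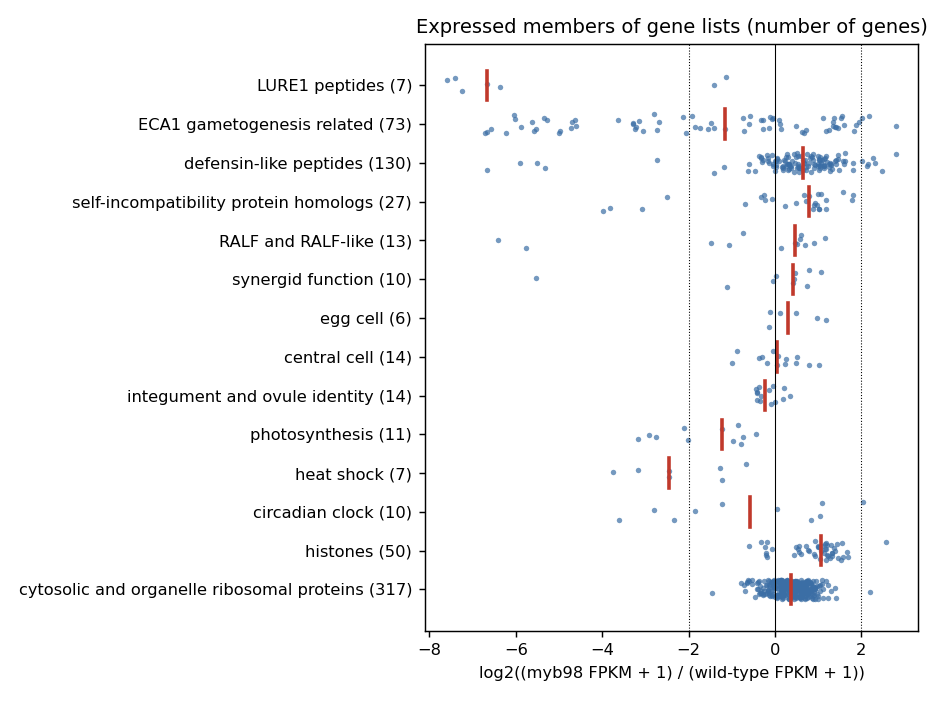
log2 ratio of myb98 to wild-type FPKM (pseudocount 1) for expressed members of 14 gene lists, 1 point per gene, with the list median in red and the number of genes in brackets. Dotted lines mark the size rule. The LURE1, ECA1-related, heat shock and photosynthesis medians (-6.68, -1.15, -2.45 and -1.22) lie below 0, and that of histones (1.08) lies above 0.

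Genes of the circadian clock, the light-harvesting complexes and the heat shock response also differed between these libraries. Of 10 expressed clock genes, 3 fell and 1 rose (median -0.58, percentile 0.01, and 0.08 with length matched). That median was -1.11 at a pseudocount of 0.1 and -0.16 at 5. The morning-phased regulators LHY (AT1G01060, 23.0 to 0.977 FPKM, 23.5-fold) and CCA1 (AT2G46830, 8.19 to 0.314 FPKM, 26.1-fold) fell with PRR7 (AT5G02810, 21.6 to 3.48 FPKM), and the evening gene ELF4 (AT2G40080) rose from a listed 0 to 3.10 FPKM, a call that ended against genes of its own length (log2 2.03 to 1.60). Evening-phased TOC1 (AT5G61380) had 8.53 and 16.0 FPKM. Of 11 expressed photosynthesis genes, 5 fell and 0 rose (median -1.22, below all random lists of either kind): LHCB2.1 (44.5 to 4.07 FPKM), LHCB2.2 (26.2 to 2.57 FPKM), CAB2 (23.64 to 2.66 FPKM), CAB3 (79.3 to 19.0 FPKM) and LHCA1 (89.7 to 20.2 FPKM). The Rubisco gene RBCS1A (AT1G67090) had 427 and 216 FPKM. LHCB2.1 and LHCB2.2 transcripts are 94.3% identical.

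Of 7 expressed heat shock genes, 4 fell and 0 rose (median -2.45, or -1.49 with a pseudocount of 5, below all random lists of either kind at a pseudocount of 1). The regulator HSFA2 (AT2G26150) went from 19.8 to 0.553 FPKM (35.8-fold), and the chaperone genes HSP70 (AT3G12580) from 63.6 to 6.21 FPKM (10.2-fold), HSP101 (AT1G74310) from 13.9 to 1.71 FPKM (8.11-fold) and HSP90.1 (AT5G52640) from 25.5 to 3.85 FPKM (6.61-fold). In the touch and wound list, 1 of 6 expressed genes rose and 0 fell (median 0.24, percentile 88.1). It was TCH4 (AT5G57560), a cell wall xyloglucan enzyme, at 3.37 and 20.8 FPKM, and TCH2 (AT5G37770) had 26.2 and 74.1 FPKM. None of 12 expressed jasmonate genes (median 0.04, percentile 65.7) and none of 3 expressed senescence genes (median -0.29, percentile 16.7) passed the rule, with AOC1 (AT3G25760) at 7.36 and 3.87 FPKM and NAP (AT1G69490) at 2.61 and 1.41 FPKM.

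Histone genes were higher as a group in the myb98 library. Of 50 expressed, 1 rose and 0 fell by the size rule, 29 had a log2 ratio of 1 or more, and the median was 1.08, or 0.81 against genes of the same transcript length (above all random lists of either kind). The gene that rose was AT5G10390 (17.2 to 107 FPKM), and HTB1 (AT1G07790) had 35.0 and 114 FPKM. Of 317 expressed ribosomal protein genes, 1 rose, AT3G56020 (57.3 to 268 FPKM, log2 2.21, or 1.74 and no longer past the rule against genes of its length), and 0 fell (median 0.37, or 0.16 against genes of the same length, percentile 99.7 with length matched). Of 47 expressed genes for pectin methylesterases and their inhibitors, 1 rose, AT3G55680 (1.84 to 10.5 FPKM, log2 2.02, or 1.56 and no longer past the rule against genes of its length), and 0 fell (median 0.55, or 0.23 against genes of the same length, above all random lists of either kind). None of 31 expressed arabinogalactan protein genes passed the rule (median 0.12, percentile 64.9), with AGP15 (AT5G11740) at 170 and 572 FPKM. Of 28 expressed subtilases 1 fell, AT5G11940 (6.47 to 0.372 FPKM, median -0.01, percentile 34.4), and none of 27 expressed AGAMOUS-like genes passed (median 0.07, percentile 61.6).

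Over all genes, 116 fell and 46 rose in myb98 ovules. Of those that fell, 48 were in a list of small secreted proteins, as were 10 of those that rose. Of the 39 genes with a log2 ratio of -4 or below, 28 were in these lists. The largest of the lists, defensin-like and ECA1-related, held 130 and 73 of the 16303 expressed genes. Members of these lists were thus frequent among the falls, and among the rises before transcript length was considered. Of the risen members, 5 defensin-like genes lost their call against genes of their own transcript length. So did AT5G36659 and AT3G01323 of the ECA1 list. Among the largest rises, HB-1 (AT3G01470), a homeobox gene, went from 0.328 to 46.7 FPKM (142-fold), and GPT2 (AT1G61800), a plastid glucose-6-phosphate translocator, from 0.435 to 42.5 FPKM (97.7-fold). JMJD5 (AT3G20810) went from 1.69 to 44.5 FPKM (26.3-fold), the clock-regulated RNA-binding protein gene GRP7 (AT2G21660) from 44.5 to 719 FPKM (16.2-fold), CYP78A9 (AT3G61880) from 0.971 to 23.2 FPKM (23.8-fold) and COR27 (AT5G42900) from 0.435 to 13.6 FPKM (31.4-fold). Exons of HB-1 overlap those of annotated neighbours. The pseudogene AT4G16870 went from 0.0963 to 8.93 FPKM.

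Some of the largest ratios belonged to very short RNAs, whose FPKM are unreliable. The small nucleolar RNA AT1G74453 went from 262 FPKM to a listed 0, SNOR105 and SNOR108 from a listed 0 to 236 and 212 FPKM, AT4G39366 to 43.6 FPKM, AT4G37095 to 67.4 FPKM and AT4G31441 to 14.96 FPKM. Of 14 genes with transcripts up to 130 nt and at least 5 FPKM in either library, 10 were listed at 0 in the other. The length classes that follow also hold only genes with at least 5 FPKM in either library. The ratio also ran with transcript length, with a median log2 ratio of 0.64 over 69 genes of 300 to 400 nt, 0.36 over 1290 genes of 600 to 1000 nt and -0.34 over 1200 genes above 3000 nt. Between 130 and 300 nt the classes held few genes and did not follow it, with medians of -0.94 over 16 genes of 130 to 200 nt and -0.23 over 16 genes of 200 to 300 nt. The fallen peptide genes are short, and since they were chosen by their fall, lying opposite to this trend was set by the choice. As whole lists, the LURE1 and ECA1 medians (-6.68 and -1.15) lay opposite to the trend. The defensin-like, RALF, thionin-like and self-incompatibility medians (0.64, 0.47, 0.50 and 0.79) went with it. The histone, ribosomal protein and defensin-like medians have the trend's direction but stayed high among random lists matched on length.

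**Figure D4:**
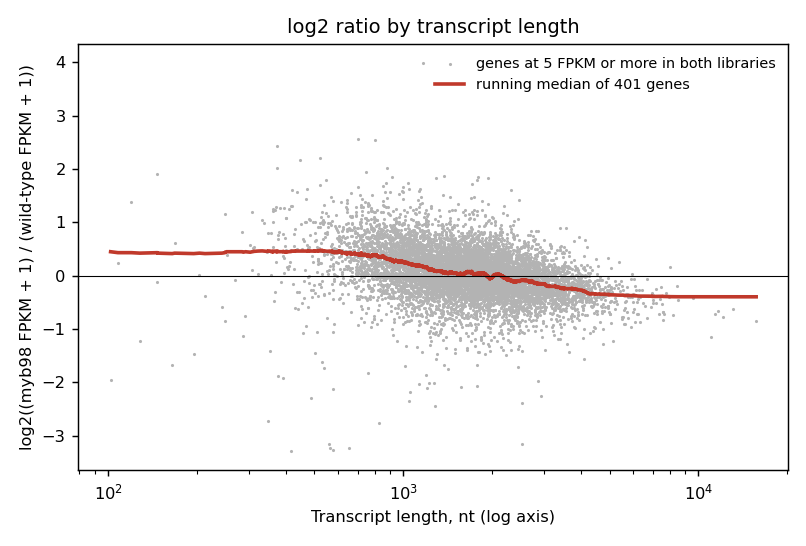
log2 ratio of myb98 to wild-type FPKM (pseudocount 1) against transcript length in nt (log axis) for genes with at least 5 FPKM in both libraries, 1 point per gene, with a running median in red. The running median does not resolve the few transcripts under 300 nt. It is above 0 at 300 to 1000 nt and below 0 above 3000 nt, with a correlation across genes of -0.386 (Spearman).

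The size rule is a rule and not a test, and the genotype is confounded with the library and with the use of the ms1 line. After centring on genes of similar transcript length, 132 genes were lower, 113 of them shared with the main 116, and 29 were higher, 28 of them shared with the main 46.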

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

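The alternatives that centre on transcript length, leave out short or non-coding transcripts, rescale without ribosomal RNA or match names without notes, and the medians over expressed list members, were chosen after the data were seen. The main values were 116 fallen genes, 46 risen genes and a LURE1 median of -6.68. At a pseudocount of 0.1 there were 189 and 147 genes and a median of -9.20, and at 5 there were 60 and 13 genes and a median of -4.41, because the pseudocount sets the ratio of genes near 0. A size rule at log2 of 1 gave 447 and 481 genes and a rule at 3 gave 62 and 12. Centring on genes of similar transcript length gave 132 lower and 29 higher genes, and 18 of the 46 risen and 3 of the 116 fallen genes lost their call. Without the note field, 1 defensin-like gene was lower in place of 5, since fewer genes carried the name. The other counts, among them 103 and 38 with protein-coding genes and 105 and 37 without transcripts under 200 nt, lay within 1.5 times the main ones. Of 25 other lists with expressed members, a pseudocount of 5 moved the median log2 ratio over those members most for heat shock (-2.45 to -1.49), the ECA1 list (-1.15 to -0.51), the clock (-0.58 to -0.16), pectin methylesterases (0.55 to 0.24), defensin-like genes (0.64 to 0.37), self-incompatibility homologs (0.79 to 0.55), synergid function (0.42 to 0.20) and endosperm (0.29 to 0.10). The moves of heat shock and the ECA1 list were over 1.5-fold on the linear scale, and those of the other 23 were not. Length centring moved them most for the ECA1 list (to -1.61), egg cell (0.30 to -0.14), defensin-like genes (to 0.20), RALF (0.47 to 0.09), thionin-like genes (0.50 to 0.13), self-incompatibility homologs (to 0.43), pectin methylesterases (to 0.23) and synergid function (to 0.14), each by less than 1.5-fold. For 9 lists with medians near 0, egg and central cell among them, the sign of that median changed with the setting. Of 124 named genes, 45 moved by more than 1.5-fold on the linear scale at a pseudocount of 0.1 and 52 at 5. The scalings shifted all genes by 0.03 (median ratio), 0.03 (trimmed mean), -0.05 (nuclear total) and 0.13 (nuclear total without ribosomal RNA) in log2, and the last gave 120 lower and 38 higher genes. The ribosomal locus AT2G01021 took 14.9% of the wild-type FPKM total and 3.97% of the myb98 total. Depth limits genes with values near 0 and short transcripts, where few fragments set the value.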

Other observations

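Tests of fewer embryo sacs, short-transcript loss, paralogs, green tissue and the length trend were chosen after the results were seen. The tests of the promoter motif, of clock-phased genes and of ribosomal protein genes were set before their values were seen.

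The MYB98 binding motif GTAACNT, searched within 500 bp upstream of the annotated start, was also counted for other sets. It was present for 23 of the 71 protein-coding genes that fell outside the LURE1 and ECA1 lists, which include other small secreted peptides and some DUF784 genes (32.4%, percentile 98.0 of lists matched on expression and GC) and 12 of all 38 that rose, ECA1-list members among them (31.6%, percentile 93.2). FKF1 (AT1G68050), chosen after its values were seen and an evening-phased photoreceptor of flowering time, went from 0.144 to 6.90 FPKM. The organelle transcripts in the table summed to 333 FPKM in the wild-type library and 147 FPKM in the myb98 library.

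The LURE1 and ECA1-family falls were weighed first. Fewer embryo sacs in the mutant sample would lower egg and central cell markers too. But their median log2 ratio was 0.18 (range -0.99 to 1.19) over the 14 with at least 5 FPKM in either library. Set against genes of their own transcript length, more of the 14 lay below 0 than above it, from -0.91 (DD46) to 0.72 (EC1.5). A small loss of embryo sacs therefore stays open. Loss of short transcripts would lower others of 250 to 700 nt, whose median was 0.51 over 465 genes with at least 5 FPKM in either library. Reads moved among the 7 LURE1 genes would keep their sum, which had a log2 ratio of -5.02. Reads moved within the ECA1 list would keep its sum, which had a log2 ratio of -1.49. Reads moved to similar genes outside these lists were not tested. The motif was present for 20 of 32 fallen protein-coding members (62.5%, against 23.7% in random lists, percentile 100), consistent with the hypothesis that MYB98 acts on these genes directly, though tandem copies share promoters and are not independent. The accession background of the ms1 line and sequence differences from the reference were not tested, so a genotype effect may be only part of the difference.

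The clock, light-harvesting and heat shock differences may reflect harvest at different times of day. In 14 other clock-phased genes outside the lists, the median log2 ratio was -1.01 for 9 morning-phased genes (8 below 0). It was 0.47 for 5 evening-phased genes (3 above 0), a difference of 1.48, which the explanation needs. The evening median is the value of a single gene, PRR3. These genes bear on the clock and did not test the light-harvesting or heat shock genes. Less green tissue carried over with the myb98 ovules cannot be told apart, since 4 carpel markers had a median of 0.024 and ovules express them too. A temperature difference and an effect of the genotype on these genes were not tested.

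Transcripts of 300 to 1000 nt were higher in the myb98 library than longer ones. The few transcripts of 130 to 300 nt with at least 5 FPKM in either library had medians below 0. The correlation of the log2 ratio with transcript length across 8701 genes was -0.386, and within 3 classes of GC content the weakest was -0.335. The trend thus held within each class of GC content, and genes are not independent replicates. The correlation restates the pattern and does not show its cause. A difference in RNA fragmentation or library preparation may contribute and was not tested. A coordinated rise of ribosomal protein genes was the biological explanation tested. These lay 0.17 above genes of their own length over 305 genes, and the median of the whole expressed list lay at percentile 99.7 of random lists matched on expression and length, which goes against the length trend as their whole difference. The excess is small and lies between the bounds set for the test, so a rise of their own stays open.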
